A study of Mus musculus with 9 samples.

How the data were processed

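The study profiled RNA of primary astrocytes from the brains of newborn C57BL/6 mice that had received medium conditioned by microglia. The microglia had been stimulated with lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4) or with hemin (the iron-containing porphyrin released from hemoglobin), and the groups are named LPS-MCM and Hemin-MCM, where MCM stands for microglia-conditioned medium. Each group held 3 libraries, made with a kit that selects polyadenylated RNA and keeps strand, per the labels' protocols. The labels call the libraries of a group separate replicates but name no separate cultures or animals, so p-values measure the spread between these samples, which can be technical.

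The authors deposited 1 table of gene-level FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) with 17730 genes and annotation columns for GO terms and KEGG pathways. The genome build mm10 and the tool DESeq are named in the submitters' processing notes, without a version. The aligner, the counting tool and the annotation are not given in the sources used here. Columns were matched to samples by the treatment word and number in their names. A further 3 columns of values had names that match no sample title, and they were used in no reported result. The medium of resting microglia, the third group of the series, was for that reason not analysed here, and neither were the comparisons with it or the overlap between the responses to both media. The planned design had 9 libraries in 1 fit and a filter on their mean. The fit and the filter used the 6 matched libraries instead, which leaves 4 residual degrees of freedom and had been planned as an alternative. This change was made after a fit with the unmatched columns had been seen, and no value of that fit is reported. Because no library of resting-microglia medium was used, higher and lower always refer to LPS-MCM relative to Hemin-MCM, and a difference can come from a change in either group.

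FPKM values are not counts, so no count model was fitted. The deposited FPKM were converted to log2(FPKM + 1), and 11688 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated variances with a mean-variance trend, 1 mean per group). The test is two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and each is given as LPS-MCM minus Hemin-MCM with its standard error (SE). Levels are means ± SD of 3 libraries. Group tests used camera, which compares the genes of a list with all other genes, with a preset correlation between genes of 0.01. Camera was also run with a correlation estimated from the data. This second run bases its test on the 4 residual degrees of freedom, so its p-values differ for that reason too. The planned design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The fit and the filter were changed later, as described above. The 25 lists (reactive and homeostatic astrocyte genes, cytokines, interferon and NF-kB genes, metabolic and stress pathways and markers of other brain cell types) held 450 genes, of which 4 had no entry in the table, and lists with at least 3 tested genes were tested. GO terms and KEGG pathways of the table with 10 to 300 tested genes were tested the same way.

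The rule for naming genes takes the 10 largest positive and the 10 largest negative differences among genes past the threshold whose groups do not overlap, with a mean of at least 5 FPKM in either group and a symbol that is no placeholder. It adds up to 4 members with the smallest adjusted p of each list and 13 fixed genes: Gfap, Vim, C3, Lcn2, Serpina3n, Gbp2, Cxcl10, S100a10, Cd109, Hmox1, Aldh1l1, Slc1a2 and Aqp4. Genes named outside this rule were chosen after their values were seen and are list members given as examples or to complete a short count, apart from Arg1, which is in no list. The values of some list members are not reported here. The KEGG pathways set beside lists were chosen after their values were seen. Coordinates come from RefSeq on GRCm38.p6, the same build as mm10, joined by gene identifier for 17618 genes, with 112 not matched.

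The table gives no read totals. Values of a gene under 0.3 FPKM step by the worth of 1 fragment: of 1578 such values up to 10 steps, 79.7% lay within 0.1 step of a whole number, where 20% would by chance. The steps put the depths of the libraries between 0.971 and 1.07 times that of the first LPS-MCM library. With transcript lengths of 214 genes that have 1 annotated transcript (GENCODE vM21), they give an estimate of 34600000 to 38100000 fragments per library. The quartiles over those genes were 33000000 and 42300000 fragments for the reference library. At the lowest depth 1 fragment on a transcript of 2 kb is worth about 0.0144 FPKM.

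The procedure was tested on simulated data with the means and residual spreads of the 11688 genes, independent noise between genes and 200 changed genes. It recovered 44% of the genes changed 1.25-fold, 80% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and 2.99% of the calls were false. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, equal totals, median-of-ratios scaling, quantile normalization, robust variances, a test against a 1.5-fold change, the replicate number as a block and leaving out each library in turn. Single genes were followed under the alternatives only where the naming rule took them. Genes named outside it, such as Tm4sf1 and Il34, have no such result, which is no sign of stability.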

Results

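RNA was measured in astrocyte cultures given medium of LPS-stimulated microglia (3 libraries) or of hemin-stimulated microglia (3 libraries). Totals ran from 348382.7 to 359093.4 FPKM per library, and the estimated depth from 34600000 to 38100000 fragments. Pearson correlations of log2(FPKM + 1) across genes were 0.9944 to 0.9968 between libraries of 1 group and 0.9809 to 0.9854 between groups. The 10 most abundant genes took 12.34 to 12.78% of the total in LPS-MCM and 10.64 to 10.9% in Hemin-MCM, and the ferritin heavy chain gene Fth1 was the most abundant in all 6 libraries.

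The comparison asks how RNA levels in astrocyte cultures given medium of LPS-stimulated microglia differ from those in cultures given medium of hemin-stimulated microglia. Of 26 cytokine and chemokine genes, 21 were higher in LPS-MCM (camera adjusted p = 6.9e-26), and so was the collagenase gene Mmp13. Interleukin 6 (Il6, chromosome 5, 30013114 to 30019975) was at 87.1 ± 2.14 FPKM in LPS-MCM and 4.07 ± 0.431 in Hemin-MCM (SD, n = 3 each), and Mmp13 (chromosome 9, 7272514 to 7283333) at 125.1 ± 20.5 and 5.52 ± 0.537. In the other direction, the chemokine gene Ccl12 (chromosome 11, 82101845 to 82103399) was at 11.8 ± 1.84 FPKM in LPS-MCM and 104.8 ± 4.997 in Hemin-MCM. The fractalkine receptor gene Cx3cr1, a gene typical of microglia, and the replication helicase gene Mcm5 were also lower in LPS-MCM.

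Of 11688 genes tested, 2400 passed the threshold, 786 higher and 1614 lower in LPS-MCM. Median-of-ratios scaling gave a more even division, with 46% of the called genes higher against 32.8%, and quantile normalization gave 45%. The test against a 1.5-fold change, with 137 genes called, gave 52.6%. Differences of at least 2-fold were fewer, at 65 genes higher and 64 lower. The libraries of the groups did not overlap in 37.5% of the tested genes, where chance gives 10%. Without the third Hemin-MCM library, 1070 genes were lower.

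Under the naming rule, the 10 largest positive differences were those of Mmp13 (log2 fold change 4.27 ± 0.10, SE), Il6 (4.12 ± 0.07), Csf3 (3.87 ± 0.10), Il1a (3.42 ± 0.09), Cxcl3 (3.16 ± 0.06), Cxcl2 (3.10 ± 0.05), Serpinb2 (2.89 ± 0.15), Ccl3 (2.89 ± 0.11), Il1b (2.84 ± 0.10) and Ptgs2 (2.81 ± 0.07). The limma adjusted p of these genes was between 3.65e-10 (Il6 and Cxcl2) and 1.16e-06 (Serpinb2). Csf3 encodes the granulocyte colony-stimulating factor, Il1a and Il1b encode forms of interleukin 1, Cxcl2 and Cxcl3 attract neutrophils, Serpinb2 encodes a plasminogen activator inhibitor and Ptgs2 the inducible cyclooxygenase. The RNA of Il1b was abundant in both groups, at 1067 ± 108 FPKM in LPS-MCM and 148.6 ± 21.1 in Hemin-MCM.

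The 10 largest negative differences under that rule were those of Ccl12 (-3.05 ± 0.09), Fcrls (-2.77 ± 0.06), Cx3cr1 (-2.34 ± 0.06), Tgfbi (-2.06 ± 0.10), Pld4 (-2.05 ± 0.06), Trem2 (-1.93 ± 0.13), Alox5ap (-1.83 ± 0.13), Hpgd (-1.71 ± 0.12), C1qc (-1.66 ± 0.10) and Cd300c2 (-1.59 ± 0.14). Their limma adjusted p lay between 1.93e-09 (Fcrls) and 3.11e-05 (Cd300c2). Fcrls, Cx3cr1 and Trem2 encode receptors of microglia and other myeloid cells, C1qc a chain of complement C1q, Alox5ap the protein that activates 5-lipoxygenase, and Hpgd the enzyme that inactivates prostaglandins. Fcrls was at 4.41 ± 0.262 FPKM in LPS-MCM and 35.8 ± 1.47 in Hemin-MCM.

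**Figure D1:**
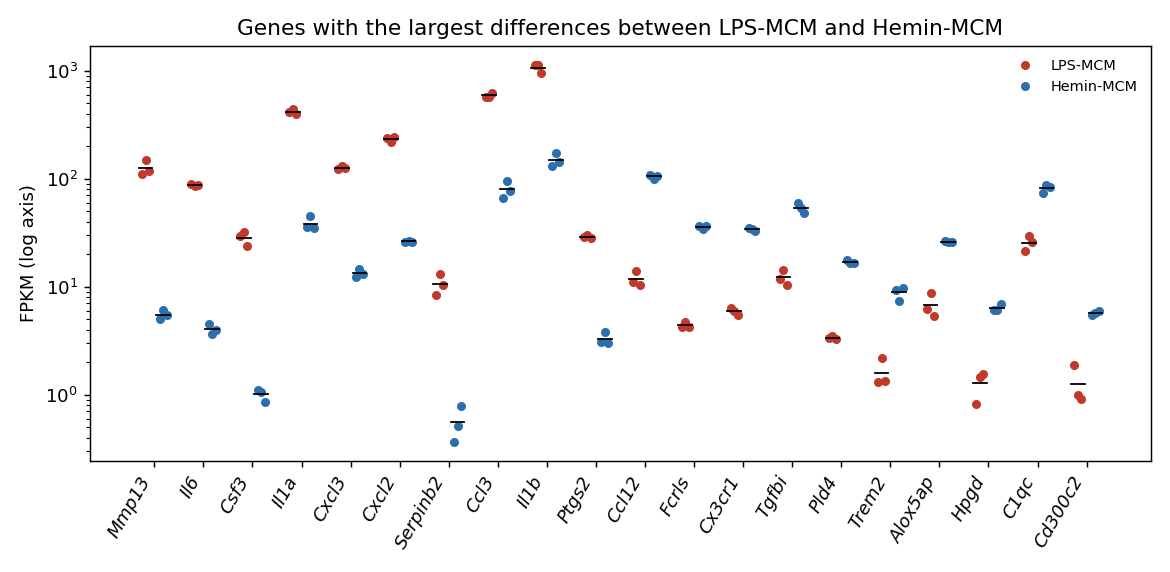
FPKM on a log axis of the 10 genes with the largest positive and the 10 with the largest negative differences. Points are the 3 libraries of each group and black lines their means. The groups lie apart in every gene because the naming rule requires it. For Il6 the means were 87.1 FPKM in LPS-MCM and 4.07 in Hemin-MCM.

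Lists were tested with camera, and their adjusted p are Benjamini-Hochberg values over the 24 lists tested. Beside these and the following lists, 16 of 19 microglia and macrophage markers were lower in LPS-MCM (adjusted p = 0.0961 with an estimated correlation), with Lyz2 at 1540 and 3303 FPKM. The libraries do not assign a transcript to a cell type. Among the other cytokine and chemokine genes, 2 were lower in LPS-MCM and 3 did not pass (adjusted over the list alone, 22 higher and 2 lower). Of the higher genes, Tnf, which encodes tumor necrosis factor, differed by 2.03 ± 0.08, Ccl4 by 2.61 ± 0.17, Ccl5 by 1.40 ± 0.11 and Cxcl1 by 1.44 ± 0.09. The lower genes were Ccl12 and Il34 (-0.25 ± 0.07). The list was also called with an estimated correlation (adjusted p = 0.0358). Of 22 target and feedback genes of the transcription factor NF-kB, 19 were higher and none was lower (20 and none adjusted over the list alone; adjusted p = 7.72e-22, and 0.0358 with an estimated correlation). Examples are the inducible nitric oxide synthase gene Nos2 (2.39 ± 0.08), the feedback inhibitor Tnfaip3 (1.11 ± 0.06), Sod2 (0.86 ± 0.05) and Nfkbiz (0.85 ± 0.05).

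Of 26 genes of the type I interferon response, 21 were higher in LPS-MCM and 5 did not pass (24 higher over the list alone). Irf7, a transcription factor of this response, differed by 1.11 ± 0.09, Zbp1 by 0.82 ± 0.06, Ifi44 by 0.61 ± 0.05 and Ifit1 by 0.53 ± 0.06. The list's adjusted p was 1.28e-17, and adjusted p = 0.0961 with an estimated correlation. Of 19 genes of antigen presentation by MHC class I, 10 were higher and 9 did not pass (12 higher over the list alone), among them B2m (0.49 ± 0.07), H2-D1 (0.45 ± 0.07) and H2-Q4 (0.44 ± 0.05). That list's adjusted p was 1.33e-09, and adjusted p = 0.0961 with an estimated correlation. The H2 class I genes, and Ifit3 and Ifit3b and the Oas genes, are related or near-identical copies whose reads the counting can divide between them, so their single values are uncertain.

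The genes used to describe reactive astrocytes did not move as 1 group, and the libraries do not show which cell type made their transcripts. Of 13 pan-reactive genes, 7 were higher in LPS-MCM and 3, Hspb1, Gfap and Vim, were lower (8 and 4 over the list alone; adjusted p = 0.00231, and 0.0887 with an estimated correlation). The call was lost under quantile normalization (adjusted p = 0.107, with 0.000206 the lowest over the alternatives). Timp1 (0.94 ± 0.06), Cxcl10 (0.48 ± 0.06), Cd44 (0.46 ± 0.05), Lcn2 (0.44 ± 0.09) and Steap4 (0.37 ± 0.05) were higher. The intermediate filament genes Gfap (-0.57 ± 0.06, 456.4 ± 23.1 against 676.2 ± 28.6 FPKM) and Vim (-0.39 ± 0.07, 1930 ± 136 against 2532 ± 26.5 FPKM) were lower. Without the low-value filter the limma adjusted p of Vim was 0.0581, the highest over the alternatives that test against no change, where the lowest was 0.000123. Serpina3n did not pass, at 398.9 ± 4.64 and 398.0 ± 7.11 FPKM. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, was at 10590 ± 720 and 7776 ± 153 FPKM. Its call was lost without the low-value filter (limma adjusted p = 0.288) and under quantile normalization, where its difference is 0 and its adjusted p is 1; the lowest over the alternatives was 0.000604.

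Of 12 A1 genes, 6 were higher, among them Srgn (0.91 ± 0.08), Iigp1 (0.72 ± 0.08) and the guanylate-binding protein gene Gbp2 (0.42 ± 0.05), and 3, Ggta1, Fbln5 and Fkbp5 (-0.68 ± 0.08), were lower (7 and 3 over the list alone; adjusted p = 0.00231, and 0.0887 with an estimated correlation). C3, the central complement component, did not pass (0.10 ± 0.07, 2449 ± 126 and 2276 ± 60.7 FPKM). The A2 list was not called (adjusted p = 0.135, and 0.284 with an estimated correlation). Of its 10 genes, 4 were higher, namely Ptgs2, Tm4sf1 (limma adjusted p = 0.0492), Ptx3 (0.90 ± 0.07) and Cd14 (0.88 ± 0.06). Another 3 were lower, namely Emp1 (-0.79 ± 0.05), S100a10 (-0.52 ± 0.06) and Cd109 (-0.31 ± 0.06). Over that list alone the counts were 4 and 3.

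Of 20 genes of homeostatic astrocytes, 10 were lower in LPS-MCM, 1 was higher and 9 did not pass (11 lower and 1 higher over the list alone; adjusted p = 0.00165, and 0.0961 with an estimated correlation). Aldoc (-0.81 ± 0.07), the potassium channel Kcnj10 (-0.57 ± 0.05) and Aldh1l1 (-0.25 ± 0.07) were lower. The adjusted p of Aldh1l1 was 0.0238 in limma and lay above the threshold under median-of-ratios scaling (0.0699) and without the filter (0.0647). It was also above it without the first LPS-MCM library (limma adjusted p = 0.058) and without the first Hemin-MCM library (0.0601), the second (0.0502) or the third (0.0996), and the lowest over the alternatives was 0.00788. The glutamate transporter gene Slc1a2 was higher (0.38 ± 0.05), and the water channel gene Aqp4 did not pass (-0.09 ± 0.07, 345.9 ± 30.1 and 368.0 ± 14.7 FPKM).

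**Figure D2:**
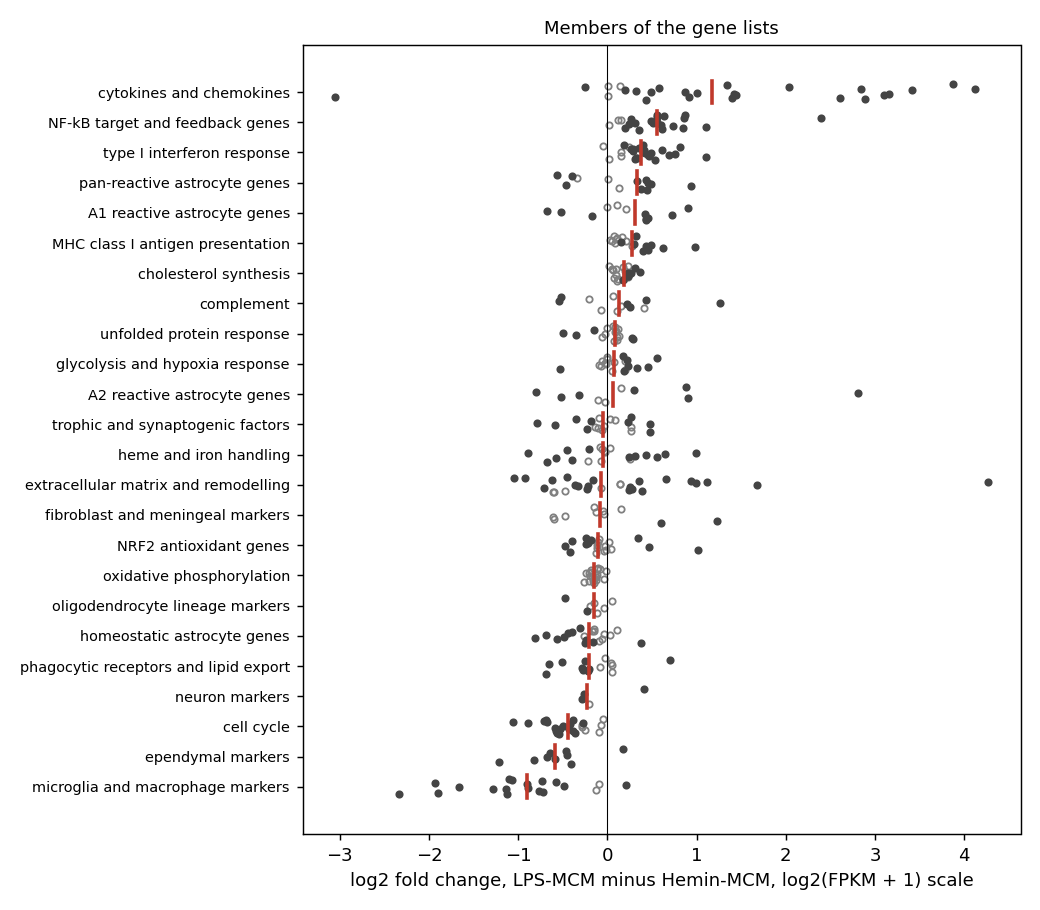
Log2 fold changes of the tested members of each list with at least 3 of them (x axis, LPS-MCM minus Hemin-MCM on the log2(FPKM + 1) scale). Filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians, from 1.17 for cytokines and chemokines to -0.895 for microglia and macrophage markers.

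Cell cycle genes were lower in LPS-MCM in 17 of 24 cases and higher in none (20 lower over the list alone; adjusted p = 6.87e-10, and 0.0358 with an estimated correlation). The helicase genes Mcm5 (-1.06 ± 0.07), Mcm6 (-0.71 ± 0.07) and Mcm3 (-0.67 ± 0.06) and the topoisomerase gene Top2a (-0.57 ± 0.05) are examples. The larger KEGG cell cycle pathway was not called, with 23 of 111 genes lower and 3 higher (camera adjusted p = 0.054, and 0.422 with an estimated correlation). Of 21 genes of cholesterol synthesis, 7 were higher and none was lower (13 higher over the list alone; adjusted p = 5.31e-08, and 0.0358 with an estimated correlation), with Nsdhl (0.37 ± 0.07), Fdft1 (0.23 ± 0.05) and Cyp51 (0.27 ± 0.07). Fdft1 had a limma adjusted p of 0.0546 without the second Hemin-MCM library, against 0.00561 as the lowest over the alternatives. Cyp51 lost its call without the first LPS-MCM (limma adjusted p = 0.0542), the second Hemin-MCM (0.0548) or the third Hemin-MCM library (0.0871) and without the filter (0.051), with 0.00881 the lowest.

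Hemin is degraded by heme oxygenase 1, whose gene Hmox1 was lower in LPS-MCM (-0.67 ± 0.06, 99.0 ± 3.71 against 158.7 ± 9.74 FPKM). Whether the stimulus itself or factors from the microglia caused this or any other difference was not tested. The heme and iron list as a whole was not called (adjusted p = 0.589, and 0.682 with an estimated correlation), with 6 of 20 genes higher and 6 lower (7 and 7 over the list alone), and its median (-0.05) and its test differ in sign. The heme exporter gene Flvcr1 (-0.89 ± 0.06) and the ferritin light chain gene Ftl1 (-0.58 ± 0.08) were lower, and Flvcr2 (0.99 ± 0.10) and the iron transporter gene Slc11a2 (0.55 ± 0.05) were higher. Ftl1 has near-identical pseudogene copies, so its value is uncertain. The NRF2 antioxidant list was not called either (adjusted p = 0.484, and 0.648 with an estimated correlation; 3 of 20 higher and 7 lower, also over the list alone). In it the cystine transporter gene Slc7a11 (1.02 ± 0.06), Gsr and Abcc1 were higher, and the peroxiredoxin gene Prdx1 (-0.47 ± 0.07) and the glutathione transferase gene Gsta4 (-0.40 ± 0.05) were lower.

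Complement genes were called higher as a list (adjusted p = 0.0205, and 0.284 with an estimated correlation), with 4 of 12 higher, namely Cfb (1.26 ± 0.06), Serping1, C1ra and C1s1, and 2 lower, among them C5ar1 (5 higher and 2 lower over the list alone). The call was lost without the second LPS-MCM library (adjusted p = 0.0837), without the filter (0.0892) and under quantile normalization (0.0658), and the lowest over the alternatives was 0.00456. The KEGG pathway of complement and coagulation was not called, with 8 of 31 genes higher and 10 lower (camera adjusted p = 0.964, and 0.979 with an estimated correlation). Genes of glycolysis and the hypoxia response were called higher (adjusted p = 0.003, and 0.431 with an estimated correlation), with 7 of 19 higher, including Bnip3 (0.55 ± 0.07) and Pfkfb3 (0.46 ± 0.04), and Pfkp lower (-0.53 ± 0.05); over the list alone 9 were higher and 1 was lower. The glycolytic enzyme gene Pfkl (0.34 ± 0.08) was among the higher genes, while Aldoa, Gapdh, Pgk1, Pgam1, Eno1, Pkm and Ldha did not pass. Pfkl lost its call without the filter (limma adjusted p = 0.0615) and without the first LPS-MCM library (0.0515). It also lost it without the first (0.0648) or the third Hemin-MCM library (0.0523), with 0.0012 the lowest over the alternatives. The KEGG pathway of glycolysis and gluconeogenesis was not called and had 3 of 44 genes higher and 10 lower (camera adjusted p = 0.409, and 0.878 with an estimated correlation). Oxidative phosphorylation genes were called lower as a list (adjusted p = 0.0162, and 0.564 with an estimated correlation) although 0 of the 20 passed limma's test on their own, also adjusted over the list alone, with 9 lower and 0 higher at an unadjusted p under 0.05. That call was lost without the third LPS-MCM library (adjusted p = 0.202) and without the first Hemin-MCM library (0.052), and the lowest over the alternatives was 0.000433. The KEGG pathway of the same name was not called, with 4 of 103 genes lower (camera adjusted p = 0.0774, and 0.807 with an estimated correlation).

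Of 27 extracellular matrix and remodelling genes, 11 were higher and 10 were lower, and the list was not called (adjusted p = 0.238, and 0.483 with an estimated correlation; 11 and 11 over the list alone). Besides Mmp13, the crosslinking enzyme gene Lox (1.68 ± 0.12) was higher, and Ccn2 (-1.05 ± 0.05) and the fibronectin gene Fn1 (-0.71 ± 0.05) were lower. The list's mean (0.172) and median (-0.0754) differ in sign. Of 14 phagocytic receptor and lipid export genes, 8 were lower, among them Mertk (-0.69 ± 0.09) and Itgb5 (-0.51 ± 0.07), and Cd36 was higher (0.70 ± 0.11), with no call (adjusted p = 0.0651, and 0.419 with an estimated correlation; 8 and 1 over the list alone). The list of trophic and synaptogenic factors was not called (adjusted p = 0.581, and 0.635 with an estimated correlation), with 4 of 18 higher, namely Thbs1 (0.47 ± 0.06), Fgf2, Vegfa and Tgfb3, and 5 lower, namely Cntf (-0.59 ± 0.08), Igf1, Sparcl1, Hbegf and Ptn. Over the list alone 6 were higher and 5 lower, and its median (-0.0491) and its test differ in sign. The unfolded protein response was not called (adjusted p = 0.0651, and 0.245 with an estimated correlation), with Atf3 and Atf4 higher and Chac1, Sdf2l1 and Pdia4 lower among 17 genes, also counted over the list alone. Atf3 lost its call without the first Hemin-MCM library (limma adjusted p = 0.0553) or the third (0.0525), with 0.00661 the lowest over the alternatives.

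Markers of other cell types were measured because cultures from newborn brain can hold them. Of 19 microglia and macrophage markers, 16 were lower in LPS-MCM, 1 was higher and 2 did not pass (17 lower and 1 higher over the list alone; adjusted p = 4.67e-15, and 0.0961 with an estimated correlation). Cx3cr1 was at 5.92 ± 0.401 and 34.0 ± 0.968 FPKM, C1qa (-1.28 ± 0.05) at 45.1 and 110.8 FPKM, and the lysozyme gene Lyz2 (-1.10 ± 0.07) at 1540 and 3303 FPKM. The Fc receptor subunit gene Fcer1g was higher (0.21 ± 0.05), and Itgam (-0.13 ± 0.05) and Ptprc (-0.09 ± 0.06) did not pass. Of 9 ependymal markers, 8 were lower and Rarres2 was higher (0.18 ± 0.05; 8 and 1 over the list alone; adjusted p = 1.49e-05, and 0.0887 with an estimated correlation). Ccdc153 (-1.21 ± 0.09), Dynlrb2 (-0.82 ± 0.07), Rsph1 (-0.58 ± 0.07) and the ciliary transcription factor gene Foxj1 (-0.40 ± 0.05) belong to the lower genes.

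Lists of oligodendrocyte lineage markers (7 tested, Cnp and Olig1 lower; adjusted p = 0.111, and 0.431 with an estimated correlation), neuron markers (4 tested, Gad1 higher and Map2 and Stmn2 lower; adjusted p = 0.494, and 0.564) and fibroblast and meningeal markers (10 tested, Lum and Dcn higher; adjusted p = 0.581, and 0.728) were not called. Over each list alone the counts were 0 higher and 2 lower for oligodendrocyte, 1 and 3 for neuron and 2 and 1 for fibroblast markers, and the fibroblast median (-0.0859) and test differ in sign. Olig1 lost its call without the first LPS-MCM library (limma adjusted p = 0.0598), the second Hemin-MCM library (0.07) or the third (0.0548), and the lowest over the alternatives was 0.00859. Map2 lost it without the first LPS-MCM library (limma adjusted p = 0.0654), the first Hemin-MCM library (0.0614) or the third (0.0568), and the lowest was 0.00674. Endothelial and pericyte markers had 1 tested gene, Pdgfrb (-0.04 ± 0.06), and no list test. Over all 24 lists tested, 14 were called and 4 with an estimated correlation: cytokines and chemokines, NF-kB genes, cell cycle and cholesterol synthesis. Other splits of the 6 libraries, which mix the groups, called up to 11 lists with the preset correlation.

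**Figure D3:**
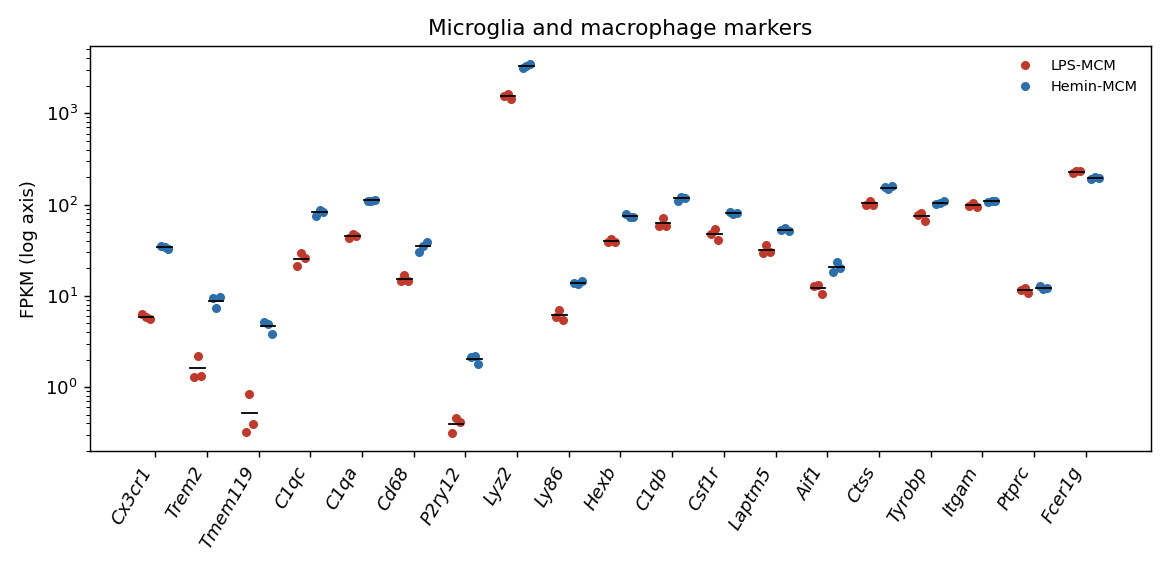
FPKM on a log axis of the 19 tested microglia and macrophage markers, ordered by log2 fold change from Cx3cr1 (-2.34) to Fcer1g (0.21). Points are the 3 libraries of each group and black lines their means; Lyz2 is the most abundant marker, at 1540 FPKM in LPS-MCM and 3303 in Hemin-MCM.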

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

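No alternative in this part was chosen after the result was seen. The planned comparisons with medium of resting microglia, their overlap and their alternatives were not run. With all 6 libraries and a test against no change, 1708 to 2496 genes changed. Testing against a 1.5-fold change left 137 genes, 72 higher and 65 lower, because it asks for a larger difference. Leaving out 1 library, which leaves fewer samples, gave 1647 to 2408 genes changed, 577 to 768 higher and 1070 to 1640 lower, with 1070 without the third Hemin-MCM library. Those fits called 13 to 15 lists. An estimated correlation left 4 lists, 0 of 70 KEGG pathways and 0 of 148 GO terms called by camera. At an unadjusted camera p under 0.05 were 64 of 305 pathways and 158 of 2996 terms tested, the latter near the share expected by chance. The estimated setting also uses the 4 residual degrees of freedom, so the lost calls do not measure correlation alone. Estimates for the pan-reactive (-0.00873), A1 (-0.0336) and cholesterol lists (-0.024) lay below the preset 0.01, yet their adjusted p rose. The A2, neuron and trophic lists, called in neither run, also had estimates below it. All other tested lists had estimates above it. The highest were oxidative phosphorylation (0.587), microglia markers (0.445), glycolysis (0.39) and type I interferon (0.358). For such lists the preset can be too low and its adjusted p too small. Over all alternatives 338 list results kept their side of the threshold, 16 lost a call and 6 gained one, in the unfolded protein response, phagocytic and neuron lists. The 338 include 24 results under robust variances that could not change, because the list test does not use that setting. They also include lists called under neither setting. Of named gene results 1487 kept it and 91 lost it, 65 of these against a 1.5-fold change, and none with a call reversed its direction. Lcn2 has a difference of 0 under quantile normalization because it holds the same rank in every library. With the replicate block 2330 genes changed and 14 lists were called, and it changed no call of a named gene or list. Deviations of same-numbered libraries correlated at -0.106 to 0.107, 1 of 3 pairs above 0.1, and 2 of 6 libraries were closest to their own number. In the simulation, where 200 of 11688 genes were changed, 44% of the smallest changes were recovered. With 2400 genes called in the data the threshold is less strict, so that share need not hold here. Small differences can still be missed.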

Other observations

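The tests on microglia markers, on the direction of the calls and on other splits were chosen after the results were seen, as was Arg1. The fit with the unmatched columns had also been seen when those tests were chosen. Of the 148 GO terms called by camera, 105 were higher and 43 lower in LPS-MCM. Among the higher terms, defense response had 31 of 47 genes higher and 1 lower (camera adjusted p = 1.62e-17, and 0.875 with an estimated correlation). Cellular response to lipopolysaccharide had 46 of 109 higher and 8 lower (adjusted p = 3.23e-12, and 0.875). Among the lower terms, genes of cilium movement were lower in 22 of 31 cases and higher in none (adjusted p = 6.13e-08, and 0.875). Genes of the axoneme were lower in 35 of 83 (adjusted p = 8.37e-08, and 0.875). In the same libraries 8 of 9 ependymal markers, among them Foxj1, Ccdc153 and Rsph1, were lower, with a median of -0.58 (camera adjusted p = 1.49e-05, and 0.0887 with an estimated correlation). Of the KEGG pathways, DNA replication had 17 of 33 genes lower (adjusted p = 3.42e-06, and 0.127 with an estimated correlation), while Cell cycle was not called, with 23 of 111 lower and 3 higher (adjusted p = 0.054, and 0.422). Lysosome had 31 of 109 lower and 4 higher (adjusted p = 0.00485, and 0.525). The IL-17 signaling pathway had 27 of 69 genes higher and 4 lower (adjusted p = 1.06e-11, and 0.124). Arg1, which encodes arginase 1, was higher (limma adjusted p = 4.32e-06), at 22.1 ± 1.54 FPKM in LPS-MCM and 8.39 ± 0.941 in Hemin-MCM.

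With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 2400 genes and the highest other split 1, and 1 of the 10 splits reached the real count. For lists, the real split called 14 and the highest other 11, and 1 of the 10 splits reached 14. The other splits mix the groups.

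In libraries labelled as astrocytes, 16 of 19 microglia markers were lower in LPS-MCM, Fcer1g was higher, and Itgam and Ptprc did not pass (camera adjusted p = 4.67e-15 for the list, and adjusted p = 0.0961 with an estimated correlation). A lower share of microglia alone would lower their abundant transcripts alike, provided that only microglia made them and their state was the same. The 16 markers at 10 FPKM or more instead spanned 2.55 on the log2 scale, with SEs of at most 0.102. They ran from Cx3cr1 (-2.34) to Fcer1g (0.21), and without Cx3cr1 from C1qc (-1.66). The limits for reading this range were set after the results were seen. These values argue against a lower share as the whole cause, and do not exclude it as a part. Median-of-ratios factors differed by -0.045 on the log2 scale between LPS-MCM and Hemin-MCM. Such scaling can move the median change of all 19 markers only little, from -0.895 as deposited to -0.851. The size of that shift argues against scaling between libraries as the source of the marker difference. A change of state in microglia that remained in the cultures, with or without a difference in their share, may account for the pattern. It could carry part of the differences in the cytokine, NF-kB and reactive astrocyte lists too, for instance the higher Il1b, Tnf, Ccl3 and Ccl4. Neither the change of state nor the size of a difference in share was tested. The cell of origin of these transcripts, and of Fcer1g and Lyz2, stays open.

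More genes were lower than higher in LPS-MCM. Of the called genes, 32.8% were higher with the values as deposited and 46% under median-of-ratios scaling. That scaling centres the genes, with a median log2 fold change of 0.000712 against -0.0386, so a near-even split follows from it whatever the source of the imbalance. Scaling between libraries and a biological difference between the media cannot be told apart here.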
